A study of Prunus persica with 84 samples.

How the data were processed

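Floral buds of the genotypes John Boy (JB) and KV021779 (LP) were sampled in 28 groups of 3 libraries, grouped by the genotype, treatment and time in the sample labels. Per the labels' protocols, RNA was extracted with a Norgen kit and libraries were made with the TruSeq Stranded mRNA kit. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trimmomatic, STAR 2.6.0 and edgeR. The deposited table holds raw counts per gene, whole numbers with no normalization. The counting tool, genome build, annotation and strand setting are not given in the sources used here. The table holds 26879 genes and 84 libraries, and 947 genes had no read.

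Total counts ran from 8021919 to 26346177 per library. Genes with low counts were left out with edgeR's filterByExpr by group, which kept 21168 genes. The 5711 others held 0.028% of all reads. Counts were scaled by TMM and fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3, limma 3.58.1) in 1 fit over all 84 libraries, with a mean per group and 56 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all tested genes within each of the 23 comparisons, and an adjusted p under 0.05 was a call. Counts of genes at least 2-fold apart are given beside it. The common dispersion was 0.00587, a biological coefficient of variation of 7.7%. CPM were computed from the deposited counts with TMM-scaled totals, and log2 CPM with a prior count of 2. A group with no count was given a floor of 3 counts over the group, which covers counting error only. On simulated data with known changes, the mean over chilling recovered 97% of genes changed 2-fold, and the comparison at 20 d recovered 89.6% of those changed 2-fold and 100% of those changed 4-fold, on 20842 genes tested. The changes were planted only in genes above a minimum mean count, and a single dispersion was used for all genes. So the recovery does not cover weakly expressed or more variable genes. Changes of 1.5-, 2- and 4-fold were planted in 67, 67 and 66 genes, in total as many up as down. TMM scaling where most genes differ was therefore not tested by it.

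Replicate pairs of log2 CPM had Pearson correlations across genes from 0.966 to 0.995. The low values came from JB 12 d replicate 3 and LP 28 d replicate 3, and without those the lowest was 0.987. No library was left out of the reported values, and the counts that rest on these libraries were also computed without them.

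Libraries were placed on the JB courses by the smallest Euclidean distance of log2 CPM to interpolated JB means, in steps of 0.1 d or 10 h, over genes past an adjusted p of 0.05 and 2-fold at some JB time (12196 genes at 22 °C, 6799 in chilling). Each JB library was left out of its own mean. Profiles simulated with noise from the interpolated JB means themselves came back with a largest error of 0.0 d over 5 placements, which leaves the error of interpolation out. That error was measured by leaving each JB time between the first and the last out of the course, for libraries of both genotypes, a check added after the data were seen. Labels were permuted within times 100000 times. Genes that rose were those with an adjusted p under 0.05 and a 4-fold rise at the peak. This grouping by peak time was chosen after the data were seen.

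Comparisons, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took PRUPE_6G242400, the DAM genes, and per main comparison the 5 largest rises and falls with a mean of at least 5 CPM that held in every shared time or had no overlap of replicates. Since the files do not pair identifiers with names, at most 2 risen and 2 fallen identifiers per comparison are printed. Of the 21 gene lists fixed by product description or identifier, only the DAM list was filled, with the 6 members the table names, a membership taken from those names after the data were seen. The reference table used here (RefSeq genes) shares no identifier with the counts and holds no descriptions, so members fixed by description could not be found. The list of cold regulators also held an identifier pattern, which PRUPE_5G090000 matches. That list and the others were not analysed here. The link of PRUPE_6G242400 to the euAP2 gene comes from knowledge of the study. The 7 models matched by the DAM identifier pattern fixed beforehand were kept out of the list, since they may overlap the named genes, and the 2 of them that passed the filter rose with chilling, against the list. The DAM list was tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, adjusted over 5 comparisons.

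Alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors within edgeR, no low-count filter, a fit of only the groups compared, the replicate number as a block, a 2-fold minimum, and leaving out each replicate number and each library. Other splits of the compared libraries were fitted alone: all 10 for 3 against 3, 100 drawn for each difference of responses, and 60 drawn for each mean over times, a number set by computing time. Results of 2 earlier runs with other numbers of draws had been seen, so the expectations for these splits count as written after the results. Python 3.11.15 was used for the courses and figures.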

Results

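Floral buds of 2 peach genotypes that differ in flowering time were profiled by messenger RNA sequencing on cut shoots. The genotypes were John Boy, written JB, and KV021779, written LP as in the sample titles. Shoots stood at 4 °C and were sampled at 0, 100, 200, 400, 600, 800 and 1000 h, and were then moved to 22 °C. At 22 °C buds were sampled at 1, 4, 8, 12, 16 and 20 d in both genotypes, and at 24 and 28 d in LP as well. JB began to bloom at 20 d and LP at 28 d. Each of the 28 combinations of genotype and time had 3 libraries, 84 in all. JB libraries held 8021919 to 26346177 counts, and LP libraries held 8823829 to 16989188. Nothing in the labels says whether replicates came from separate trees, so the p-values measure the spread between these samples, which may be technical in part. No replicate pair agreed within sampling noise, since the chi-square per degree of freedom ran from 1.41 to 24.67 over 84 pairs.

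The series title names an euAP2 gene, a member of the APETALA2 family of transcription factors. That gene is taken here as PRUPE_6G242400, from knowledge of the study, since the count table gives only the identifier. PRUPE_6G242400 stood at the same level in both genotypes before chilling, with 34.7 ± 0.83 CPM in JB and 35 ± 1.6 in LP (SD, n = 3). Within 100 h of chilling it rose in LP to 60 ± 2.1 CPM, and it reached 68.8 ± 2.3 CPM at 400 h. In JB it stayed between 27.8 ± 2.1 CPM, at 200 h, and 39.9 ± 3.2 CPM, at 600 h. The difference between genotypes at 0 h was 0.01 ± 0.1 on the log2 scale (SE, adjusted p = 0.969 in edgeR's quasi-likelihood test). At 200 h PRUPE_6G242400 was 1.21 ± 0.1 higher in LP (adjusted p = 1.1e-17), and the mean over all 7 chilling times was 0.67 ± 0.04 higher (adjusted p = 1.16e-26). From 0 to 1000 h PRUPE_6G242400 rose by 0.71 ± 0.1 in LP (adjusted p = 3.8e-09), against 0.08 ± 0.1 in JB (adjusted p = 0.552). The test of that difference gave 0.63 ± 0.14 (adjusted p = 0.00038).

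At 22 °C PRUPE_6G242400 fell in both genotypes. In JB it went from 36.5 ± 3.8 CPM at 1000 h of chilling to 18.9 ± 0.37 CPM at 20 d, a log2 change of -0.95 ± 0.11 (adjusted p = 4.49e-12). In LP it went from 57.0 ± 2.7 CPM to 27.9 ± 2.5 CPM at 20 d and to 6.56 ± 0.61 CPM at 28 d, and the change to 28 d was -3.11 ± 0.12 (adjusted p = 7.82e-35). When each genotype began to bloom, the level in LP was lower than in JB by -1.52 ± 0.13 on the log2 scale (adjusted p = 3.8e-16). The expression profiles of these 2 groups may differ in stage, so this value may mix stage with genotype. PRUPE_6G242400 was also compared at each shared warm time. PRUPE_6G242400 was higher in LP at 1 d (0.30 ± 0.1, adjusted p = 0.0138), 8 d (0.29 ± 0.11, adjusted p = 0.0272), 16 d (0.51 ± 0.12, adjusted p = 0.000106) and 20 d (0.56 ± 0.11, adjusted p = 7.58e-06). It gave -0.02 ± 0.1 at 4 d (adjusted p = 0.935), and was lower in LP at 12 d alone (-0.58 ± 0.11, adjusted p = 6.93e-06). The mean over the 6 shared warm times was 0.18 ± 0.04 higher in LP (adjusted p = 0.000298). The 12 d value rests in part on JB replicate 3, which stood apart from the other JB 12 d libraries, and without it the difference was -0.78.

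**Figure D1:**
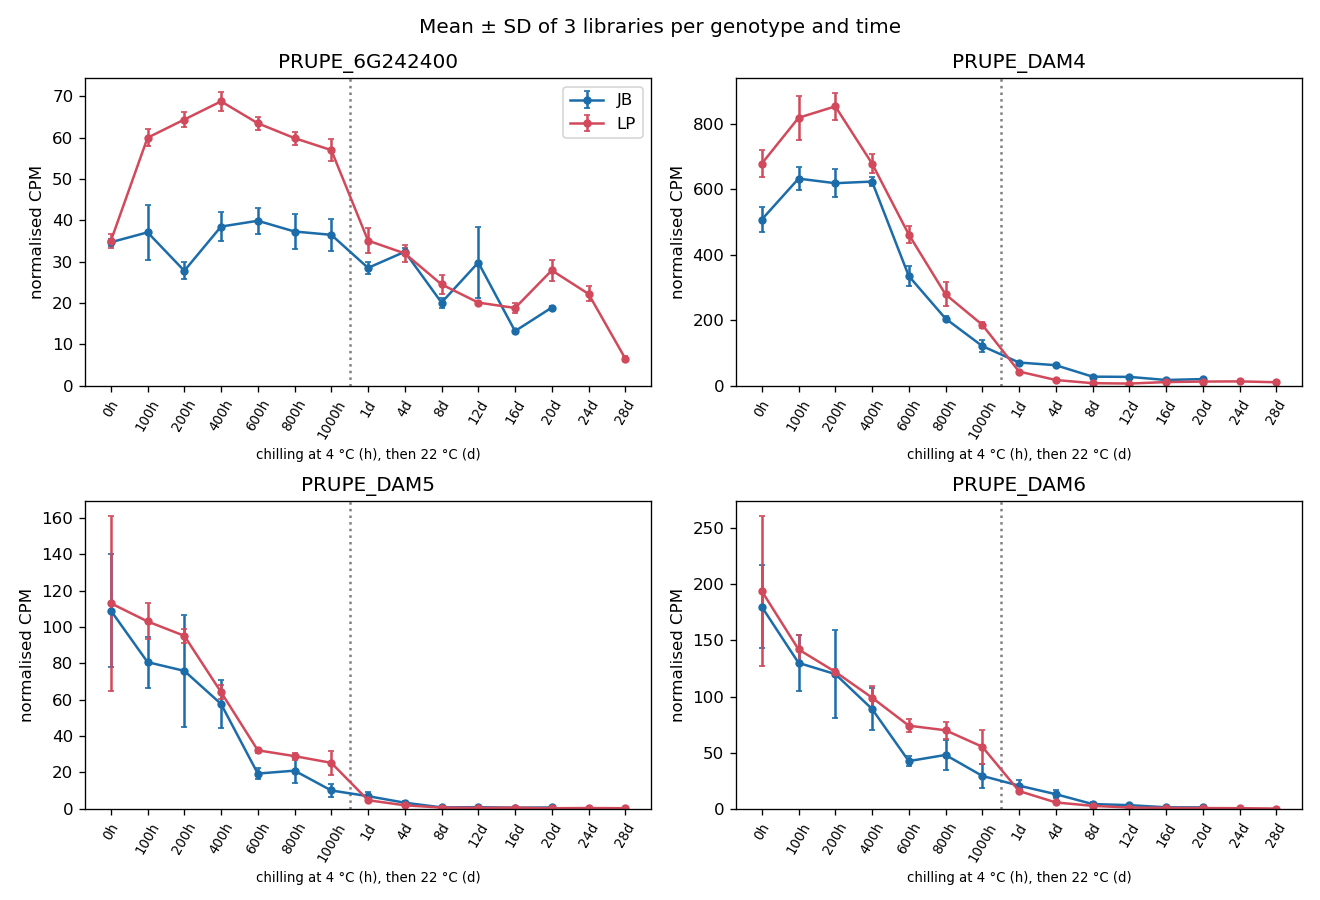
Normalised counts (CPM, scaled to the library total) of PRUPE_6G242400, PRUPE_DAM4, PRUPE_DAM5 and PRUPE_DAM6 against time at 4 °C and then at 22 °C, as the mean and SD of 3 libraries per genotype and time, with a dotted line at the move to 22 °C. PRUPE_6G242400 separates the genotypes from 100 to 1000 h of chilling, while the 3 DAM genes end chilling below their start in both, PRUPE_DAM4 after higher early values.

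The count table names 6 DAM genes, the dormancy-associated MADS-box genes, which are tied to winter dormancy of buds. PRUPE_DAM4, PRUPE_DAM5 and PRUPE_DAM6 were the abundant members, and all 3 were lower at 1000 h than at 0 h in both genotypes. PRUPE_DAM4 stood higher at first, at 633 ± 36 CPM at 100 h and 624 ± 15 CPM at 400 h in JB, and at 854 ± 41 CPM at 200 h in LP. PRUPE_DAM4 fell from 508 ± 37 to 121 ± 19 CPM in JB between 0 and 1000 h (n = 3), and from 679 ± 40 to 186 ± 10 CPM in LP. PRUPE_DAM5 fell from 109 ± 31 to 9.99 ± 3.8 CPM in JB and from 113 ± 48 to 25.2 ± 6.7 CPM in LP. PRUPE_DAM6 fell from 180 ± 37 to 29.2 ± 11 CPM in JB and from 194 ± 67 to 55.2 ± 15 CPM in LP. In JB 5 of the 6 members passed the test as lower at 1000 h, and 6 did when adjusted over the list alone. Camera placed the list below other genes in JB chilling (adjusted p = 0.0201), but with an estimated correlation the adjusted p = 0.279.

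At the end of chilling these 3 genes were higher in LP, PRUPE_DAM4 by 0.62 ± 0.09 (adjusted p = 5.92e-08), PRUPE_DAM5 by 1.35 ± 0.27 (adjusted p = 2.96e-05) and PRUPE_DAM6 by 0.92 ± 0.23 (adjusted p = 0.000714) on the log2 scale. The fall itself was smaller in LP for PRUPE_DAM5, by 1.33 ± 0.34 (adjusted p = 0.00161), and the call was lost without replicate 1 of every group (0.35, adjusted p = 0.609). For PRUPE_DAM6 the same test gave 0.82 ± 0.31 (adjusted p = 0.0319), which turned to -0.03 without replicate 1 and lost the call in 6 of the 12 fits that left out 1 library. PRUPE_DAM4 showed 0.20 ± 0.13 in that test (adjusted p = 0.232). At 22 °C, in the mean over the shared warm times, 3 of the 6 DAM genes passed the test as lower in LP and 3 did not pass. The order turned for PRUPE_DAM4. PRUPE_DAM4 was lower in LP at each of the 6 shared warm times, with a mean difference of -1.31 ± 0.05 (adjusted p = 2.93e-35) and 6.36 ± 0.23 against 26.8 ± 3.1 CPM at 12 d. PRUPE_DAM1 and PRUPE_DAM2 rose in JB from 1000 h to 20 d at 22 °C, by 2.83 ± 0.39 (adjusted p = 1.07e-09) and 4.72 ± 0.65 (adjusted p = 1.61e-09), to 4.63 ± 0.38 and 2.93 ± 0.8 CPM. DAM genes lie in a family of similar copies, and reads shared between copies could not be traced in the counts, so their single values are uncertain.

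Genotype differences over chilling covered most tested genes when no size was set. Averaged over the 7 chilling times, 14676 of 21168 genes differed at an adjusted p under 0.05, 7829 higher and 6847 lower in LP. The balance was the opposite among the 2221 genes at least 2-fold apart, 703 higher and 1518 lower in LP. The balance over all calls turned without replicate 1 of every group, with 6565 higher and 6681 lower. It also turned in the fit of only the groups compared, with 7038 higher and 7115 lower. It held with DESeq2, its size factors, no low-count filter, the replicate block, and without replicate 2 or 3. The largest differences were near absence in a genotype. PRUPE_8G080600 had 43.8 ± 9.2 CPM in LP (SD, n = 21) and 1 count in all over the 21 JB chilling libraries. These SDs run over the libraries of all 7 times, so they mix change over time with replicate spread. PRUPE_7G000900 had 39.1 ± 3.8 CPM in LP and 1 count over the same JB libraries. PRUPE_4G020200 had 79.7 ± 6.3 CPM in JB and 4 counts over the 21 LP libraries, and PRUPE_8G008700 had 32.3 ± 19 CPM in JB and 1 count in LP. The files do not pair these identifiers with gene names. Per time, genes at least 2-fold apart numbered 960 higher and 1206 lower in LP at 0 h, and 964 higher and 2169 lower at 200 h.

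Within warming, differences between the genotypes were most numerous at 20 d, though the number did not rise at every step. Genes at least 2-fold apart numbered 661 higher and 2175 lower in LP at 1 d, 1608 and 1968 at 4 d, 1003 and 1654 at 8 d, 2310 and 2465 at 12 d, 1782 and 3477 at 16 d, and 3398 and 3769 at 20 d. Averaged over the 6 shared warm times, 14530 genes differed, 7656 higher and 6874 lower in LP, with 812 at least 2-fold higher and 1725 at least 2-fold lower in LP. The balance over all calls turned with DESeq2 size factors, with 6837 higher and 7513 lower. It also turned with DESeq2, with 6842 higher and 7919 lower. It held in the other alternatives that set no fold minimum and left out no single library. PRUPE_4G092800 had 42.4 ± 12 CPM in LP (SD over the libraries of all 6 shared warm times, n = 18) and no count in the JB libraries. That makes it at least 2990-fold higher against a floor of 3 counts over the group. PRUPE_2G059000 was likewise at least 1870-fold higher in LP. When LP at 28 d was set against JB at 20 d, each at its own start of bloom, 2387 genes were at least 2-fold higher and 2437 lower in LP. LP at 28 d was placed at 15.8 ± 1.13 d on the JB warm course, so this count may mix stage with genotype.

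**Figure D2:**
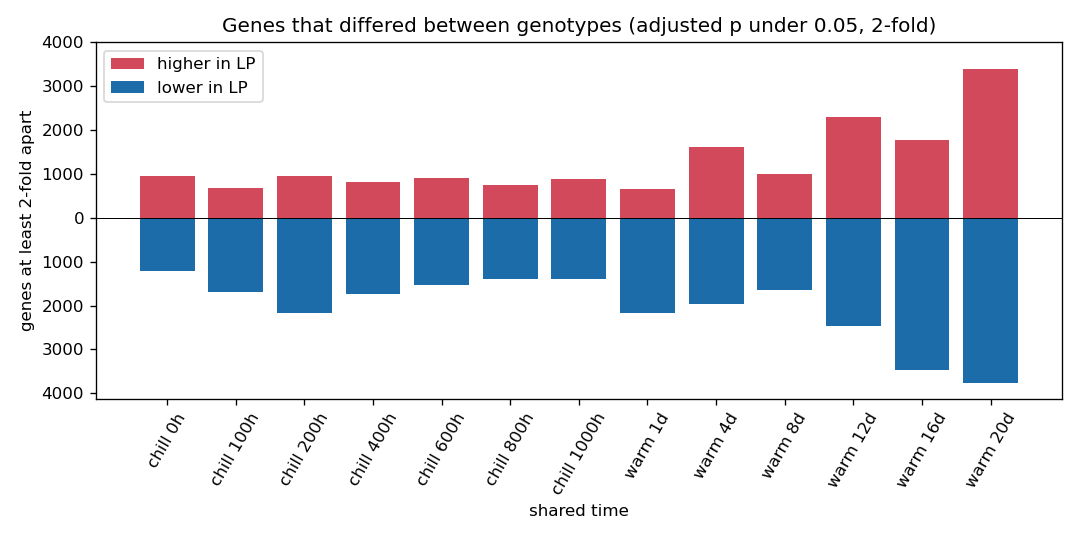
Numbers of genes at least 2-fold higher (up) or lower (down) in LP than in JB at an adjusted p under 0.05, at each of the 13 shared times. The bars are longest at 20 d, with 3398 higher and 3769 lower genes.

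Many genes changed in the buds of both genotypes during chilling. No shoots were sampled over this time without chilling, so cold was not separated from elapsed time on cut shoots. Between 0 and 1000 h, 1803 genes rose and 2653 fell at least 2-fold in JB, and 1217 rose and 2428 fell in LP. In JB, PRUPE_5G090000 rose from 1.08 ± 0.6 to 20.8 ± 2 CPM (log2 change 4.29, adjusted p = 1.08e-25) and PRUPE_7G142100 from 0.879 ± 0.31 to 15.2 ± 1.8 CPM (4.10, adjusted p = 3.93e-24). PRUPE_5G090800 fell from 25.3 ± 2.1 to 0.0374 ± 0.065 CPM, and PRUPE_I003100 from 11.1 ± 1.3 to 0.0374 ± 0.065 CPM, each with 1 count left in the 3 libraries. The response differed between genotypes for 6719 genes, 3637 more positive and 3082 more negative in LP, of which 633 responded at least 2-fold more positively and 836 at least 2-fold more negatively in LP. That number fell to 2986 without replicate 1 of every group and to 3827 without replicate 2. The balance over all calls turned with DESeq2 size factors, with 3314 more positive and 3363 more negative in LP. It also turned with DESeq2, with 3381 and 3431. It held in the other alternatives that set no fold minimum and left out no single library.

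Warming changed more genes than chilling did. By 20 d, 4703 genes rose and 3413 fell at least 2-fold in JB, against 3653 and 1947 in LP. At 28 d LP reached 4864 risen and 2947 fallen genes. In JB, PRUPE_6G000500 rose from no count to 681 ± 52 CPM and PRUPE_3G279500 from no count to 638 ± 25 CPM, at least 6770-fold and at least 6330-fold against the floor. PRUPE_4G194200 fell from 368 ± 29 CPM to no count in JB, at least 3860-fold, and PRUPE_3G021100 fell from 147 ± 4.9 CPM to 0.0298 ± 0.052 CPM. The response at 20 d differed between genotypes for 12161 genes, 3233 more positive and 2786 more negative in LP at 2-fold. PRUPE_4G194200 was among them. In LP it had 20.7 ± 1.8 CPM at 1000 h and 43.3 ± 3.7 CPM at 20 d (difference of responses, adjusted p = 1.2e-60).

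LP libraries lay behind JB on the warm course. Each library was placed at the day whose interpolated JB mean profile was nearest, over 12196 genes that changed in JB. JB libraries left out of their own mean, with the other 2 libraries of that day kept, fell near their true day, except at 12 d, where the mean was 11.1 ± 1.5 d (SD, n = 3). Placement between sampled days was less exact. With the whole day left out of the course, JB libraries of 1 d and 4 d all lay at 3.1 d, those of 8 d at 8.6 to 8.8 d, those of 12 d at 6.0, 6.0 and 8.8 d, and those of 16 d at 16.3 d. On such courses the mean difference between LP and JB over the 5 days from 1 to 16 d was -5.01 d (permutation p = 2e-05), against -5.61 d over the same days with the day kept. LP at 8 d lay at 2.7 d, LP at 12 d at 2.3 d, LP at 16 d at 5.6 ± 0.06 d and LP at 20 d at 6.2 d. LP at 24 d lay at 13.3 d and at 28 d at 15.8 ± 1.13 d. Over the 6 shared days the mean difference was -6.96 d (two-sided permutation within days, p = 1e-05, the smallest that 100000 permutations can give). Here JB libraries had replicates of their own day in the course and LP libraries had none. The error of the 12 d libraries with their day left out was close to that size, so the difference in days is rough. JB 12 d libraries at 6.0 d lay near LP at 20 d that way. Another measure put LP at 20 d near JB at 12 d. Over 4052 genes changed at least 4-fold in JB by 20 d, LP at 20 d showed a median of 34.6% of that log2 change. JB showed 24.1% at 8 d and 34.0% at 12 d. So the lag of LP at 20 d may be smaller than its position gives. Single days, 3 against 3 libraries, cannot go below an exact p of 0.1. Relative to each genotype's own level at 1000 h, LP at 8 d lay at 1.9 d and LP at 12 d at 0.9 ± 0.06 d. On that scale LP at 16 d lay at 6.3 ± 0.06 d and LP at 20 d at 6.8 d. LP at 24 d also depended on the setting, at 10.7 ± 2.34 d by Pearson correlation and 7.6 ± 0.12 d relative to each genotype's own level at 1000 h. Without JB 12 d replicate 3 and LP 28 d replicate 3 it lay at 8.3 ± 1.18 d, and of these 2 only the JB library builds the course, so the 13.3 d rests on 1 library. LP libraries had mean distances of 0.92 to 1.19 log2 units to the nearest JB profile. JB libraries had 0.31 to 0.55 with replicates of their day in the course, and 0.62 to 1.17 with their day left out, a range that overlaps that of LP. The overlap came from JB at 12 and 16 d alone. At 1, 4 and 8 d, JB libraries lay at 0.62 to 0.76 with their day left out and LP libraries at 0.92 to 1.08, without overlap.

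On the chilling course LP libraries of early times lay nearest to later JB times, though no JB profile was close to them. LP at 0 h lay at 20 h on the JB course, at 100 h at 700 h, at 400 h at 710 h, and at 1000 h at 913.3 ± 5.77 h (SD, n = 3). Over the 7 times the mean difference was 246.67 h (two-sided permutation within times, p = 1e-05), again with replicates of the same time in the course for JB alone. With each time from 100 to 800 h left out in turn, JB libraries were placed with an error of up to 110 h, and LP at 100, 200 and 400 h stayed at 700 to 710 h. LP libraries then lay 0.95 to 1.07 log2 units from the nearest JB profile, against 0.4 to 0.8 for JB libraries, without overlap. So the positions in hours name the least distant JB profile and do not show that LP buds resembled it. Over these 5 times the mean difference was 318 h (permutation p = 2e-05), against 348 h with the time kept. The size depended on the baseline. With each genotype taken relative to its own level at 0 h, LP at 100 h lay at 213.3 ± 265.58 h (SD, n = 3, from 60 to 520 h) and the mean difference was 103.81 h (permutation p = 0.0078).

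**Figure D3:**
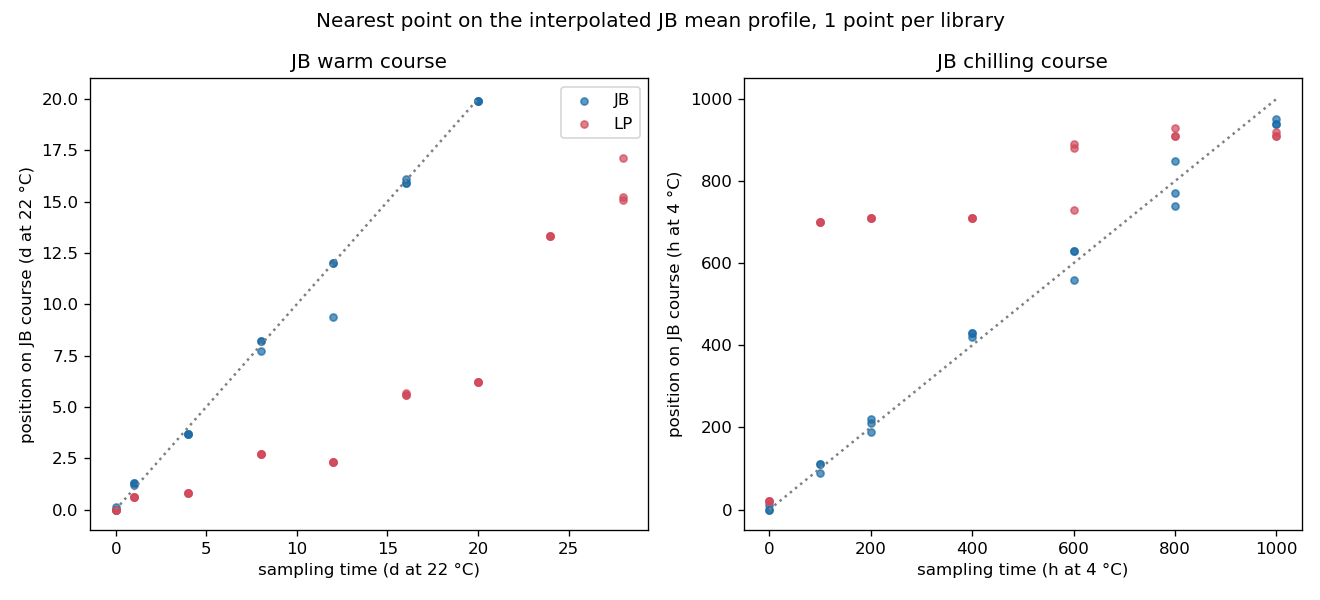
Position of each library on the JB warm course (left, d at 22 °C) and the JB chilling course (right, h at 4 °C) against its sampling time, 1 point per library, with a dotted line where both are equal. LP libraries lie below the line at 22 °C, at 6.2 d when sampled at 20 d.

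Genes that rose in JB at 22 °C mostly peaked later in LP. At least 4-fold rises over 1000 h of chilling, with a peak mean of at least 5 CPM, were found for 2883 genes in JB. Of the 473 with a JB peak at 12 d, 422 peaked later in LP (89.2%), 17 on the same day and 34 earlier. Of the 515 with a JB peak at 16 d, 485 peaked later in LP (94.2%), and 257 had not risen 2-fold in LP by 20 d, but 24 had not by 28 d. Of the 1379 with a JB peak at 20 d, 171 had not risen in LP by 28 d (12.4%). LP was sampled for longer, which leaves room for later peaks, so the reverse selection was made too. Most genes with an LP peak at 16 or 20 d peaked earlier in JB, while the earlier LP peaks showed no single direction. Of 332 genes with an LP peak at 16 d, 294 peaked earlier in JB and 29 later, and of 292 with an LP peak at 20 d, 239 peaked earlier in JB. At an LP peak of 12 d, 38 of 71 peaked earlier in JB and 18 later. At 8 d, 40 of 104 peaked earlier and 43 later, at 4 d, 82 of 200 earlier and 65 later, and at 1 d, 0 of 142 earlier and 62 later. The first and last shared days leave no room for 1 of the directions. Between them, a late LP peak leaves more JB days before it than after it, and an early one fewer. So the counts at 16 and 20 d cannot separate a lag from the number of days on each side. At an LP peak of 4 d more genes peaked earlier than later in JB, though 1 d was the only earlier day. Genes are not independent replicates, and the 12 d group grew to 617 genes without JB 12 d replicate 3 and LP 28 d replicate 3.

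**Figure D4:**
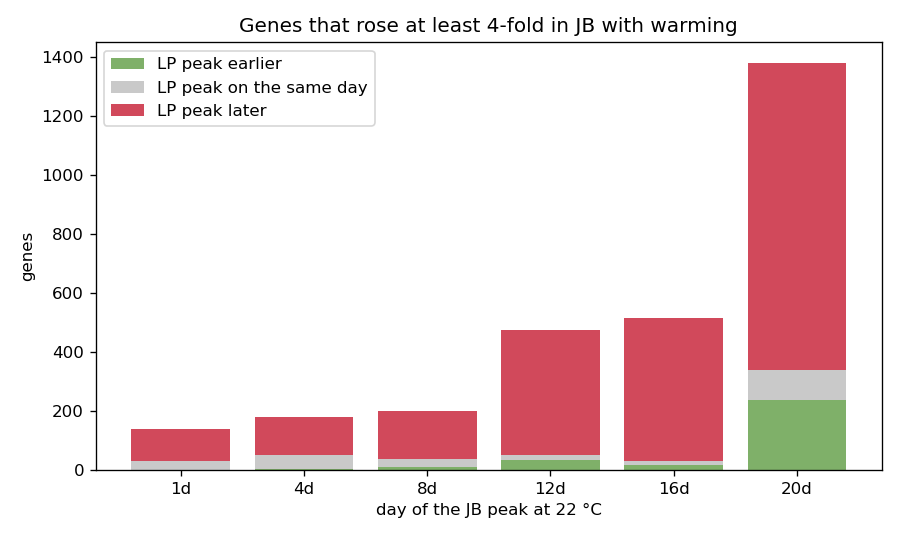
Number of genes that rose at least 4-fold in JB at 22 °C, by the day of their JB peak, split by whether the LP peak came earlier, on the same day or later. Later LP peaks make up 422 of 473 genes at 12 d and 485 of 515 at 16 d.

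During chilling, 416 genes rose at least 4-fold in JB over 0 h, and 207 of them did not rise 2-fold in LP at any chilling time (49.8%). The largest group, 265 genes, peaked at 200 h in JB, and 144 of these did not rise in LP (54.3%). Of 148 genes that rose in LP, 7 did not rise in JB (4.7%).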

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

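All tests of explanations in this part were chosen after the results were seen, except the estimate of LP RNA in JB 12 d replicate 3 and the placement at equal depth, which were written down before they were run. The chilling response differed between genotypes for 6719 genes, and the response to 20 d at 22 °C for 12161, by tests of the difference of responses. PRUPE_6G242400 rose more with chilling in LP by 0.63 on the log2 scale. PRUPE_DAM5 and PRUPE_DAM6 fell less with chilling in LP, by 1.33 and 0.82, but without replicate 1 of every group these were 0.35 and -0.03, and the PRUPE_DAM6 call was lost in 6 of 12 fits without 1 library. PRUPE_DAM2, PRUPE_DAM4 and PRUPE_DAM5 had more negative responses to 20 d at 22 °C in LP, at -3.45, -1.31 and -2.77. PRUPE_DAM2 and PRUPE_DAM5 rest on few counts there, at 0.521 ± 0.22 and 0.234 ± 0.11 CPM in LP at 20 d. The warm calls of both were lost without replicate 1 of every group, at adjusted p = 0.175 and 0.121, and leaving out 1 library ended the call in 2 of 12 fits for PRUPE_DAM2 and in 8 of 12 for PRUPE_DAM5.

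Other splits of the same libraries were fitted without the remaining groups, so their real counts differ from those of the fit over all groups, by up to 1.28 times (9590 against 12252 at 12 d of warming). For the mean over chilling, 1 of 60 splits, the real one, gave as many genes (14153, against 2082 in the highest other). For the mean over warm times it was also 1 of 60 (14572 against 2550). A random grouping of these libraries is thus argued against for both. Whether replicates came from separate trees is not known, so the splits do not bear on other trees of the genotypes. For the differences of responses, 2 of 100 splits, the real one included, gave as many genes, in chilling (5511, highest other 9206) and at 22 °C (12160, highest other 13242). Genotypes were exchanged within each time, so a split that kept them at 1 time and mixed them at the other still held genotype differences. These splits therefore cannot decide on the difference of responses. The higher split in each exchanged the genotypes in full at 1 of the times, which turns the comparison into a sum of genotype differences and points to the structure of the samples. For the 19 comparisons of 3 against 3 libraries, 1 of 10 splits, the real one, gave as many genes, with real counts from 7074 to 15188 and 0 in the highest other. With 10 splits the share cannot fall under 0.05.

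JB 12 d replicate 3 stood apart from the other 2 libraries of its group, at 9.4 d on the JB course against 12.0 d. A label exchanged with a JB 8 d library is argued against, since the JB 8 d libraries lay at 8.2 d at most. LP RNA in this library is argued against too, since 67 genes at least 8-fold higher in LP at every shared time put its share at 0.0553%. Less advanced buds reached no decision, since its deviation pointed toward JB 8 d with a cosine of 0.65 across genes, but also toward JB 16 d with 0.28, and with 12 d left out of the course it lay at 8.8 d, later than the other 2 at 6.0 d. So replicates 1 and 2 may be the ones apart from the course, which the 3 libraries cannot settle.

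More genes were at least 2-fold lower than higher in LP during chilling (1518 against 703). Over all called genes the fit of all groups had the opposite balance, 7829 higher and 6847 lower. That balance was not stable, with 6565 higher and 6681 lower without replicate 1 of every group. In the fit of only the groups compared it was 7038 higher and 7115 lower. Loss of LP alleles in read assignment would lower the same genes at all times, but genes 2-fold apart at all 13 shared times had a ratio of lower to higher of 0.96 (150 against 156). Weak expression is argued against as the whole source, since at a mean of at least 5 CPM the ratio was 2.03. That LP expresses these genes only later reached no decision, since 76.9% came to 50% of the JB chilling mean in LP at some warm time, but 52.4% (796 genes) did so at some chilling time in LP already. Of the genes higher in LP, 57.6% likewise came to 50% of the LP chilling mean in JB at some warm time, so later expression stays open and the test does not single it out.

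LP libraries lay behind JB at 22 °C. Offsets present before warming are argued against as the whole source, since relative to each genotype's own level at 1000 h LP at 20 d lay at 6.8 d, and so is depth, since with every library thinned to 8019579 counts in tested genes LP at 20 d lay at 6.1 d. A later run of the JB programme with no other difference is argued against too, since 134 genes, 62 of them with a mean of at least 5 CPM, kept all JB and LP libraries at least 2-fold apart over all times. Whether LP runs the programme later apart from such genes cannot be told apart from a changed programme. Without them the smallest distance of an LP 28 d library to a JB profile was 1.13 log2 units. That is near the highest of JB libraries placed with their own time left out, 1.17. Over all course genes the highest such value came from JB at 16 d alone. The genotype difference in bloom date stays among the open biological explanations, as a hypothesis.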

How the results depend on the processing

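Added after the data were seen were the single-library checks of both means, the 8-fold rises, the sets without JB 12 d replicate 3 and LP 28 d replicate 3, the positions relative to each genotype's own start, and those with the library's own time left out. Outside the 2-fold minimum, counts of changed genes kept within 1.5 times in all but 3 recomputations. The balance of higher and lower calls was less stable, and turned in some settings for both means and for the chilling difference of responses, among others. Without replicate 1, 2 or 3 of every group the chilling difference of responses gave 2986 to 7304 genes and the 100 h genotype difference 5584 to 7651, and with single libraries left out too the highest were 7340 and 8308. The cause was not tested, and fewer libraries lower the power. Replicate numbers did not pair the samples: 0 of 19 pairings had all correlations over 0.1, and the replicate block gave 0.982 to 0.999 times the counts of the 23 comparisons (14637 for the mean over chilling).

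With a 2-fold minimum, which removes small changes by construction, genotype counts were 2221 (mean over chilling), 2537 (mean over warm times), 2166, 2354, 3133, 2545, 2440, 2139 and 2280 at the 7 chilling times and 2836, 3576, 2657, 4775, 5259 and 7167 at the 6 shared warm times in order. Response counts were 4456 (JB chilling), 3645 (LP chilling), 1469 (their difference), 8116 (JB 20 d), 5600 (LP 20 d), 7811 (LP 28 d), 6019 (difference at 20 d) and 4824 (LP 28 d against JB 20 d).

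PRUPE_6G242400 over chilling (0.67) is under 2-fold. Its 0 h difference had no sign, with -0.003 with no low-count filter and -0.04 to -0.01 in the recomputations without a replicate that turned it. Over all such recomputations it reached 0.05. The JB chilling change of PRUPE_6G242400, also uncalled, ran from -0.02 to 0.15. The PRUPE_DAM6 difference of chilling responses ran from -0.03 without replicate 1 to 1.38 without replicate 2, and missed the threshold under DESeq2 (0.79, adjusted p = 0.12). The DAM list in JB chilling had adjusted p = 0.279 with an estimated correlation. Fry, which tests whether members move 1 way and not against other genes, gave 4.46e-05 (mean over chilling), 1.85e-16 (mean over warm times), 2.88e-09 (JB warming, where 2 members were higher and 3 lower) and 3.3e-08 (difference of warm responses). None of these 4 passed camera (adjusted p = 0.334, 0.104, 0.334 and 0.104) or camera with an estimated correlation (0.514, 0.352, 0.514 and 0.352). At 8-fold, 1807 genes rose in JB with warming, of which 29.9% had not risen in LP by 20 d and 5.4% by 28 d, and 166 rose with chilling. With the block, the PRUPE_DAM5 difference of warm responses missed the threshold (-2.78, adjusted p = 0.0559). Depth limits PRUPE_DAM5 at 22 °C, with 8 counts over the 3 LP libraries at 20 d.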

Other observations

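The test of neighbouring genes was chosen after the result was seen. Models PRUPE_1G531500 and PRUPE_1G531700, which match a DAM identifier pattern, ran against PRUPE_DAM4 to PRUPE_DAM6 in chilling. PRUPE_1G531700 went from 0.435 ± 0.086 CPM at 0 h to 2.19 ± 0.42 at 1000 h in JB (SD, n = 3), and from 1.18 ± 0.51 to 6.75 ± 0.36 in LP. PRUPE_1G531500 went from 0.197 ± 0.34 to 2.53 ± 0.24 CPM in JB and from 0.322 ± 0.24 to 4.90 ± 1.6 in LP. Both were near 0 after 8 d at 22 °C. They rest on few counts, 1364 and 1413 over 84 libraries, and may share reads with the named DAM genes, which was not tested.

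Genes at least 2-fold apart at all 13 shared times were uneven over the chromosomes. Chromosome 2 held 113 of them, 37.0%, with 12.1% of the tested genes (odds ratio 4.42, Fisher's exact test, adjusted p = 1.21e-28 over 8 chromosomes). Fisher's test takes genes as independent, while these genes lay next to each other more often than in shuffles, so that p-value is too small. Chromosome 1 held 19, 6.2%, with 22.3% of tested genes. In identifier order, 65 pairs of such genes were direct neighbours, against a mean of 7.5 and a highest of 20 in 10000 shuffles within chromosomes (permutation p = 0.0001, the smallest they can give). A window of 50 tested genes on chromosome 2, from PRUPE_2G052700 to PRUPE_2G059400, held 19. As a hypothesis, blocks of the chromosomes that differ between the genotypes may underlie these 65 pairs. Families of similar neighbouring copies would give the same pattern and were not separated from it.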
